A study of Mus musculus with 4 samples.

How the data were processed

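Messenger RNA was measured by stranded RNA sequencing in RAW264.7 cells, a mouse macrophage-like line derived from a virus-induced leukaemia tumour. The 4 libraries form 2 groups of 2: control cultures, and cultures given 0.5 mM 1,5-anhydroglucitol (1,5-AG) for 24 h. 1,5-AG is a naturally occurring polyol that differs from glucose by the lack of the hydroxyl group on carbon 1. Groups and replicate numbers come from the sample labels. No culture time was found for the controls, so a match to the 24 h of the treated cultures is not established. Nothing in the labels says that replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, total RNA was taken with Trizol and libraries were made with a stranded mRNA kit, in which selection for polyadenylated RNA leaves most non-polyadenylated RNA under-represented.

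The values the authors deposited are FPKM (fragments scaled to exon length and to the fragments of each library), 1 column per library, for 21523 Ensembl gene identifiers. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks and HTSeq were used with the genome build mm10. The versions, the role of each tool, the strand setting and the annotation release are not given in the sources used here. Of the identifiers, 21508 matched GENCODE release M21, which gave gene symbols, gene types and coordinates on the same build, and 15 did not match. When each FPKM was multiplied by the merged exon length of its gene in that release, 99.3% of genes came out as whole multiples of the value of 1 fragment in all 4 libraries, within a tolerance of 0.02 fragments. This gave the number of fragments assigned to genes: 15163807 and 16228673 in the control libraries, and 14616556 and 15112965 in the 1,5-AG libraries. At this depth 3 fragments in a gene with 2 kb of exon correspond to 0.0924 to 0.103 FPKM. These floors cover counting error only, as fragments without molecular identifiers are not independent molecules. Whole values show no splitting of a fragment between genes, but how reads that match several near-identical copies were treated is not given in the sources used here, so values of paralogs, pseudogenes and overlapping genes are uncertain. FPKM is also a share of each library, so a change in a few abundant genes shifts all others. The 10 most abundant genes took 5.63% to 6.12% of the fragments per library.

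Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the group as the only term and a variance trend on mean expression (lmFit and eBayes). Genes with a mean FPKM of at least 1 over the 4 libraries entered the test, 11120 in all. Of rows that share a symbol, the row with the highest mean was used, which left out 8 rows. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values of single genes quoted in the text are from this limma fit. Fold changes are 1,5-AG minus control on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. A permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single-gene evidence rests on limma's pooling of variance across genes, with 3.05 prior degrees of freedom. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists, and beside it with an estimated correlation and with fry. Genes counted as past the threshold when adjusted over the list alone are given where lists are described.

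The test, the 31 pathway lists, 7 lists of markers of other cell types and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes in each direction with the largest fold change among those past the threshold with separate groups, leaving out predicted genes and pseudogenes. It also took up to 4 members past the threshold from each list, and the 2 members with the smallest p from a called list with none past it. Lyz2, Cd68, Csf1r, Adgre1 and the 5 most abundant genes were added. Had fewer than 5 genes passed in a direction, the 5 with the smallest p would have been added. A gene that the rule returned is not reported here. Genes named outside this rule are said to have been chosen after their values were seen. The fixed osteoclast list names carbonic anhydrase 2 by a symbol that the annotation does not use, so Car2 was absent from that test, and a version with it was computed afterwards.

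The test was run on simulated fragments for 11059 genes with known changes, drawn from the means and depths of these libraries. It called 4.17% of genes changed 1.25-fold, 46.9% of those changed 1.5-fold, 90% of those changed 2-fold and 93.6% of those changed 4-fold. Of 10835 unchanged genes it called 10. A simulated changed set had a camera adjusted p of 5.64e-18 with the preset correlation and of 0.832 with the estimated one. Camera with an estimated correlation thus did not recover this simulated change with 2 libraries per group. Simulated genes varied independently, so the preset correlation was not tried on genes that vary together. In the data the estimated correlation of the 11 lists called with the preset one ran from -0.0567 (heat shock) to 0.342 (chemokines).

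Alternatives fixed in advance were other pseudocounts, filters, scalings, variance models and thresholds, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were limma voom on the recovered fragments, removal of each library's loess trend on GC content and length, the same with the replicate block, protein coding genes only, and the osteoclast list with Car2. Parent genes of pseudogenes were sought with BLAST+ 2.17.0 among transcripts of the same annotation release.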

Results

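RAW264.7 mouse macrophages given 0.5 mM 1,5-AG for 24 h were compared with control cells by RNA sequencing, with 2 libraries per group. The control libraries held 15163807 and 16228673 gene-assigned fragments, and the 1,5-AG libraries 14616556 and 15112965. Genes listed at 0 FPKM numbered 3241 and 2984 in the control libraries and 3629 and 3473 in the 1,5-AG libraries. Pearson's r across genes, which are not independent replicates, was 0.992 between the control libraries, 0.990 between the 1,5-AG libraries and 0.988 between libraries of different groups. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 3.39 in the control group and 2.46 in the 1,5-AG group, against 8.73 to 9.88 between groups. The first principal component held 45.9% of the variance and separated the groups. The second held 29.4% and set the 1,5-AG libraries apart from each other (11.6 and -12.7), with the control libraries at 1.35 and -0.266. Macrophage genes were abundant in all libraries. Cd68 had 499 ± 1.20 FPKM in control and 475 ± 5.08 with 1,5-AG, and Csf1r 258 ± 0.237 and 239 ± 2.29 (SD, n = 2 per group throughout). Their log2 fold changes of -0.07 and -0.11 did not pass the test, nor did that of Adgre1, the gene of the macrophage marker F4/80, at -0.32. Of the marker genes of fibroblasts, T and NK cells, B cells, neutrophils, dendritic cells, epithelium and liver, and erythroid cells found in the table, Lck (mean 1.26 FPKM) and Ighm (45.1 FPKM) exceeded 0.308 FPKM, the mean of S100a8.

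The single comparison of the design asks how 1,5-AG changes the transcriptome of these cells. Abca1, the membrane transporter that exports cholesterol and phospholipid, rose with 1,5-AG from 4.26 ± 0.621 to 19.0 ± 0.659 FPKM (log2 fold change 1.93, SE 0.09, adjusted p = 0.00953). Plin2, a coat protein of lipid droplets, rose from 22.8 ± 1.01 to 44.1 ± 0.581 FPKM (0.92). Car2, a carbonic anhydrase, rose from 368 ± 0.772 to 849 ± 12.8 FPKM (log2 fold change 1.20, SE 0.03, adjusted p = 0.00225). Lyz2, the lysozyme of macrophages, fell from 4488 ± 92.9 to 3048 ± 66.9 FPKM (-0.56, SE 0.04, adjusted p = 0.0169), and the protease gene Ctsk fell from 46.3 ± 0.642 to 29.1 ± 0.529 FPKM (-0.65).

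In all, 162 of 11120 genes passed the limma test at an adjusted p of 0.05, 90 higher and 72 lower with 1,5-AG. In each of the 162 both 1,5-AG libraries lay on the same side of both control libraries, which held for 49.6% of tested genes against 33.3% expected by chance. Being called all but requires this separation, so it adds no evidence for the called genes. The share over tested genes comes from genes that are not independent. Changes were small: the median absolute log2 fold change of the called genes was 0.50, and 19 genes reached 1 (15 higher, 4 lower). Of the called genes 122 were protein coding, 56 higher and 66 lower, and 28 were pseudogenes, all 28 higher, out of 882 tested. With each library's trend on GC content and length removed, 17 pseudogenes were higher and 4 lower. The limma call count depended on each library: it was 3 without control replicate 1, 2 without control replicate 2, 2 without 1,5-AG replicate 1 and 10 without 1,5-AG replicate 2. It was 5 without the variance trend and 0 without a filter on low values (2628 genes at unadjusted p under 0.05), while voom on the recovered fragments called 917 (404 higher, 513 lower).

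**Figure D1:**
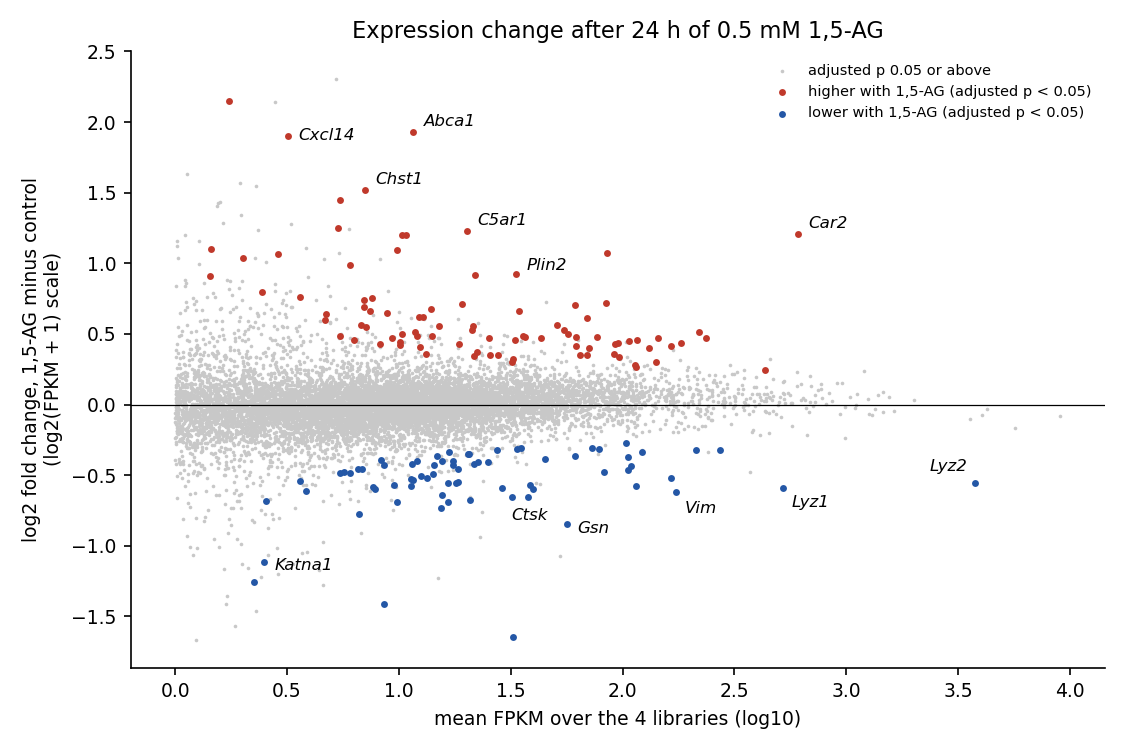
Log2 fold change (1,5-AG minus control, log2(FPKM + 1) scale) against the log10 of the mean FPKM over the 4 libraries for the 11120 tested genes; each point is a gene, red and blue points are the 90 higher and 72 lower genes past the limma threshold and grey points the rest. Car2 and Lyz2 stand out among abundant genes, at 1.20 and -0.56.

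Among the largest increases by the naming rule, Cxcl14, a chemokine gene on chromosome 13 (56288643 to 56296551, mm10), went from 0.767 ± 0.0125 to 5.60 ± 0.128 FPKM (log2 fold change 1.90), with 21 and 23 fragments in control and 147 and 157 with 1,5-AG. Abca1 lies on chromosome 4 (53030787 to 53159895) and Car2 on chromosome 3 (14886273 to 14900770). Chst1, a sulfotransferase gene, rose by 1.52, C5ar1, the receptor of complement fragment C5a, by 1.23, Ptgs1, the constitutive cyclooxygenase, by 1.20 and the kinase gene Dmpk by 1.20. The rule also returned 3 very short genes with few fragments. Mir1968 (68 bp, inside Grtp1 on the same strand) had 0 fragments in both controls and 4 and 3 with 1,5-AG. Mir7651 (64 bp, inside Zmiz2 on the same strand) had 2 and 3 against 8 and 8, and the 5S ribosomal RNA copy n-R5s183 had 1 and 1 against 4 and 4. Among the largest decreases were Katna1, a subunit of the microtubule-severing enzyme katanin (3.78 ± 0.304 to 1.21 ± 0.180 FPKM, -1.11), and Gsn, the actin-severing protein gelsolin (72.8 ± 1.86 to 40.2 ± 4.76 FPKM, -0.85). The rule further gave the transcription factor gene Klf4 (-0.78), Ms4a6d (-0.73), the cytokine receptor gene Il13ra1 (-0.69), Lhfpl2 (-0.69), Filip1l (-0.68) and Cd300ld (-0.66). The immunoglobulin segments Ighd4-1 (11 bp, 8 and 9 fragments against 3 and 2) and Ighj2 (100 bp, 41 and 40 against 24 and 23) fell by 1.65 and by 0.67. Under voom on the recovered fragments Mir7651, n-R5s183, Ighd4-1 and Ighj2 no longer passed.

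In the list of cholesterol efflux and LXR target genes, 4 of 15 tested members rose and 0 fell. Adjusted over the list alone 6 were higher and 1 lower. Besides Abca1 and Plin2 these were Abcg1, which exports cholesterol to lipoproteins (41.1 ± 1.10 to 61.2 ± 2.70 FPKM, 0.56), and Scd1, a fatty acid desaturase (51.4 ± 0.0634 to 71.9 ± 2.59 FPKM, 0.48). The list as a whole did not pass: its median of -0.08 was negative while its mean of 0.23 and the camera direction were positive (camera adjusted p = 0.117), and fry gave an adjusted p of 0.0152. The list of cholesterol biosynthesis and uptake genes fell as a set, with 22 of 25 members negative and a median of -0.08 (camera adjusted p = 0.00597; adjusted p = 0.423 with an estimated correlation), although 0 of its members passed alone and 1 was lower when adjusted over the list alone. That call was lost without 1,5-AG replicate 1 (camera adjusted p = 0.112). Its member with the smallest p, Mvd, had -0.27 (adjusted p = 0.0581). Of 26 genes of fatty acid synthesis, storage and oxidation, Acaca, which makes malonyl-CoA, rose (0.36) and the desaturase gene Fads1 fell (-0.31), with 3 higher and 3 lower adjusted over the list alone. Cd36, a scavenger receptor for oxidised lipoproteins and fatty acids, rose from 5.12 ± 0.296 to 8.86 ± 0.811 FPKM (0.69).

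**Figure D2:**
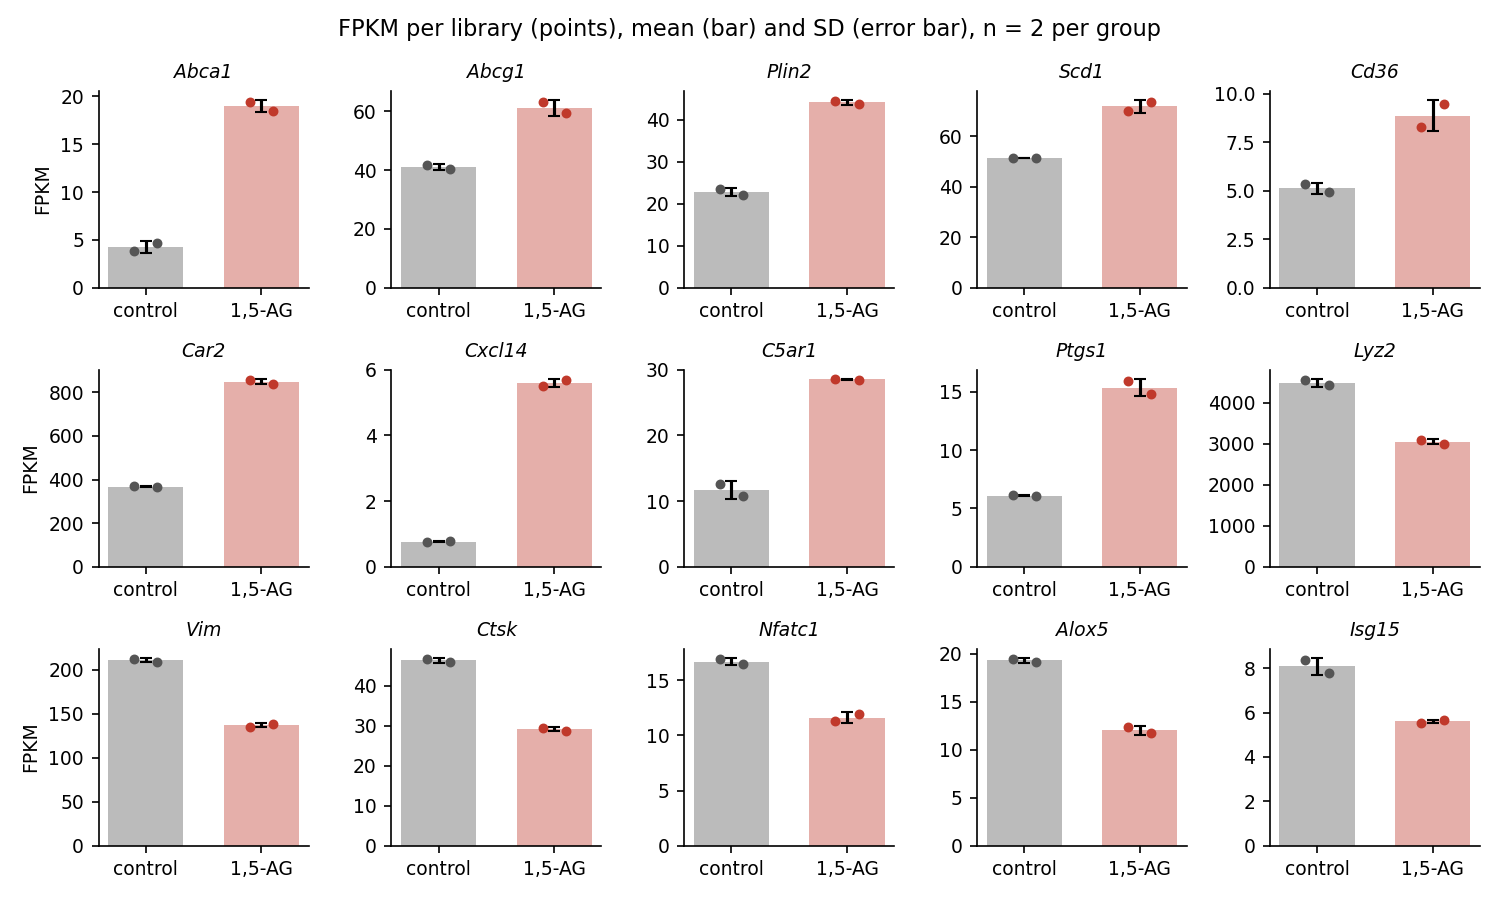
FPKM of 15 genes in control (grey) and 1,5-AG (red) libraries; points are single libraries, bars are means and error bars are SD (n = 2 per group). Abca1 goes from a mean of 4.26 to 19.0 FPKM and Lyz2 from 4488 to 3048 FPKM, and Alox5 was added after its values were seen.

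The integrated stress response, unfolded protein response, hypoxia and heat shock lists were higher as sets, and the oxidative stress and p53 lists were not called. In the integrated stress response list 25 of 27 tested members were positive, with a median of 0.21 (camera adjusted p = 1.21e-09; adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 14 were higher and 1 lower. Asns, the asparagine synthetase gene, rose (61.0 ± 3.43 to 81.0 ± 2.71 FPKM, 0.40), whereas the transcription factor gene Atf3 fell (13.6 ± 0.350 to 9.13 ± 0.292 FPKM, -0.53). In the unfolded protein response and ER chaperone list 3 of 21 rose and 18 were positive (camera adjusted p = 1.43e-06; adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone 11 were higher and 1 lower. These 3 were Hspa5, the chaperone BiP (395 ± 5.00 to 468 ± 5.17 FPKM, 0.24), Pdia4 (0.28) and Creld2 (0.44). Ribosome biogenesis and MYC-linked genes had 31 of 33 members positive and a median of 0.11 (camera adjusted p = 6.41e-08; adjusted p = 0.342 with an estimated correlation), with 0 called alone and 1 higher when adjusted over the list alone. Odc1, the ornithine decarboxylase gene, had 0.28 (adjusted p = 0.0581) and Gar1, a component of small nucleolar ribonucleoproteins, 0.27 (adjusted p = 0.0932). In the hypoxia list Ddit4 (0.60), the growth factor gene Vegfa (0.44) and Ero1l (0.32) rose among 18 tested, 7 higher when adjusted over the list alone (camera adjusted p = 0.00905; adjusted p = 0.423 with an estimated correlation). The heat shock list had 11 of 16 positive and a median of 0.09, with 0 called in either adjustment (camera adjusted p = 0.0221; adjusted p = 0.423 with an estimated correlation). Hsp90aa1 had 0.18 (adjusted p = 0.110) and Hsph1 0.19 (adjusted p = 0.137). The oxidative stress and NRF2 list had 12 members positive and 12 negative (camera adjusted p = 0.863), and the p53 list 11 positive and 8 negative (camera adjusted p = 0.863). The heat shock list, with a mean of 0.0469, lost its call under quantile normalization (mean 0.0327) and without the variance trend (mean 0.0469). It also lost it without control replicate 2 (mean 0.0296) and without 1,5-AG replicate 1 (mean 0.0441). The hypoxia list, with a mean of 0.116, lost its call without 1,5-AG replicate 2 (mean 0.0795).

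The interferon-stimulated, antigen presentation, macrophage identity and osteoclast lists were lower as sets. Of 26 interferon-stimulated genes 23 were negative, with a median of -0.14 (camera adjusted p = 3.03e-05; adjusted p = 0.342 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein (8.07 ± 0.387 to 5.60 ± 0.0708 FPKM, -0.46), and Oas3, an antiviral RNA sensor (-0.40), fell, and 5 were lower when adjusted over the list alone. The antigen presentation list had 13 of 15 negative and 0 called, with 5 lower adjusted over the list alone (camera adjusted p = 0.00280; adjusted p = 0.342 with an estimated correlation). The protease gene Ctss had -0.21 (adjusted p = 0.0938) and the class I regulator Nlrc5 -0.29 (adjusted p = 0.137). In the macrophage identity and phagocytosis list 3 of 26 members fell and 2 rose, or 12 and 4 adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.00280; adjusted p = 0.342 with an estimated correlation). Lyz2, Lyz1 (-0.59) and Gpnmb (-0.37) fell; Lyz1 and Lyz2 are closely related neighbours that could share reads. Ncf1, a subunit of the NADPH oxidase, rose (141 ± 1.32 to 188 ± 1.90 FPKM, 0.41), as did the integrin gene Itgb2 (0.43), named after its value was seen. In the osteoclast list Ctsk and the transcription factor gene Nfatc1 (16.7 ± 0.342 to 11.6 ± 0.484 FPKM, -0.49) fell among 9 tested, 4 lower when adjusted over the list alone (camera adjusted p = 0.00344; adjusted p = 0.423 with an estimated correlation). With Car2, itself an osteoclast gene, included under its annotated symbol, that call ended (camera adjusted p = 0.0770). The mean of the list went from -0.24 to -0.09, while its median went from -0.18 to -0.17.

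In the chemokine and receptor list, 2 of 8 tested members rose and 2 fell, or 6 and 2 adjusted over the list alone, and the set was higher (median 0.31, camera adjusted p = 0.0142; adjusted p = 0.460 with an estimated correlation). Cxcl14 and Ccl9 (80.0 ± 1.58 to 102.8 ± 1.21 FPKM, 0.36) rose, whereas Cx3cr1, the fractalkine receptor (-0.27), and Cxcl16 (-0.39) fell. The chemokine list lost its call with a filter at a mean of 5 FPKM (mean 0.03, camera adjusted p = 0.693) and without a filter (0.18, camera adjusted p = 0.0915).

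**Figure D3:**
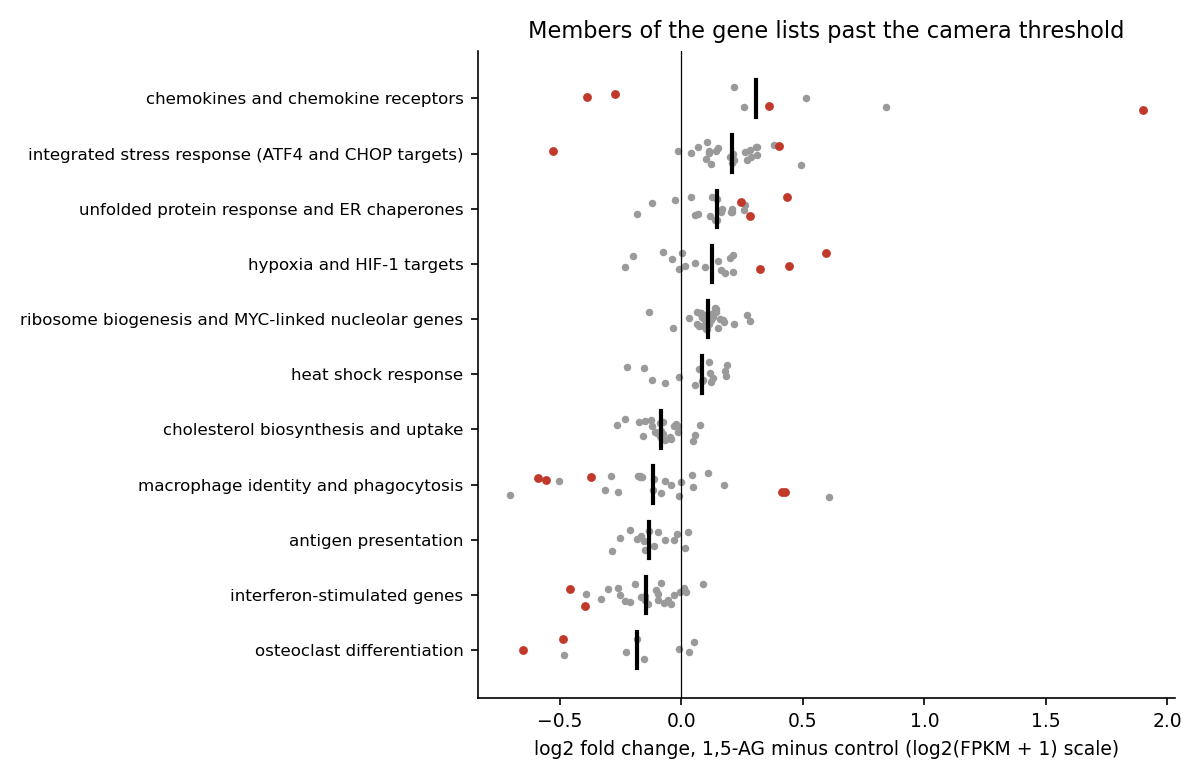
Log2 fold change (1,5-AG minus control, log2(FPKM + 1) scale) of each tested member of the 11 lists past the camera threshold with the preset correlation; points are genes, red where the gene itself passed the limma threshold, and black bars are medians, from -0.18 for the osteoclast list to 0.31 for chemokines. The chemokine list holds red points on both sides of 0, with Cxcl14 at 1.90.

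The other 20 lists did not pass, with camera adjusted p from 0.0585 for glucose transport and glycolysis to 0.864 for NF-kB feedback and signalling genes. Of 27 glucose transport and glycolysis genes Aldoc, an aldolase, fell (-0.31) and 0 rose, with 3 higher and 1 lower adjusted over the list alone. None of 26 pentose phosphate, polyol and glycogen genes passed in either adjustment (camera adjusted p = 0.168). Of 7 tested inflammatory cytokine and mediator genes 0 passed, and 1 was higher adjusted over the list alone (camera adjusted p = 0.442). The pattern recognition list (9 members positive and 14 negative, camera adjusted p = 0.316) and the alternative activation list (5 and 5, camera adjusted p = 0.509) were not called either. The pattern recognition list had 0 members past the threshold, or 2 lower adjusted over the list alone. Of 10 tested alternative activation genes Cd36 and Vegfa rose and Klf4 fell, or 3 higher and 1 lower adjusted over the list alone. Single members that passed in other uncalled lists were Ier3 (0.66), Ctsd, the lysosomal protease cathepsin D (0.44), Idh1, the cytosolic isocitrate dehydrogenase (0.47), Plk2 (0.91), Etv5 (0.66), mt-Nd4l (0.65), Klf6 (-0.40), Anxa1 (-0.36) and Vim, the intermediate filament vimentin (211 ± 2.41 to 137 ± 2.22 FPKM, -0.62). The gene mt-Nd4l (297 bp, 31 and 31 fragments in control, 50 and 47 with 1,5-AG) overlaps mt-Nd4 on the same strand. Its nuclear copy Gm10222, 100% identical over the aligned part, also rose (1.10), so the value of mt-Nd4l is uncertain. Camera's direction differed from the sign of median and mean in the NF-kB, alternative activation and p53 lists. Of the most abundant genes, mt-Co1 (-0.08), Eef1a1 (-0.03), mt-Nd1 (-0.07) and the small RNA gene Gm23935 (-0.17) did not pass; under quantile normalization mt-Nd1 and Eef1a1 changed sign.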

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

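The voom, GC and length, protein coding and Car2 alternatives were chosen after the data were seen; the others were planned. The number of genes past the threshold, 162, was 160 and 179 with pseudocounts of 0.1 and 0.01, 162 with median-ratio scaling, 145 with quantile normalization, 211 with robust variance and 183 with the GC and length trend removed. It was 0 without a filter on low values, 360 at a mean FPKM of at least 5, 5 without the variance trend, 2 to 10 with 1 library left out, 917 with voom, 412 among protein coding genes only (163 higher, 249 lower), 19 with an absolute log2 fold change of at least 1 and 2023 at unadjusted p under 0.05, where 556 are expected by chance. Deviations of same-numbered libraries correlated at 0.0124 across genes, so no large effect shared by equal numbers was visible. Whether equal numbers mark a shared culture or day is not given in the labels. The replicate block gave 310 genes, and 76 together with the GC and length trend removed. The cause of these differences was not tested, apart from the thresholds, the fewer genes and the fewer libraries that some settings impose. Leaving out 1 library leaves a lone sample assumed to vary like the other group. Of the 162 calls 0 reversed in the refits. Voom tested 161 of them and shared 146. Over the 70 named genes and all refits 790 values kept their side of the threshold, 359 lost it and 22 gained it with the same sign, and 4 changed sign. Car2 passed in each fit with 1 library left out. Lists past the threshold, 11, numbered 0 with an estimated correlation, 9 to 15 in the refits and 6 with fry. Of the 11, fry called chemokines, interferon-stimulated genes, unfolded protein response and integrated stress response. Each of the 11 kept its direction in the refits. Chemokines lost their call without a filter and at a mean FPKM of at least 5, the osteoclast list with Car2, and heat shock under quantile normalization, without the variance trend, without control replicate 2 and without 1,5-AG replicate 1. Hypoxia lost its call without 1,5-AG replicate 2 and cholesterol biosynthesis without 1,5-AG replicate 1. Of genes not called, the log2 fold change of Eef1a1 was 0.0789 and the log2 fold change of mt-Nd1 was 0.118, then past the threshold, under quantile normalization. The log2 fold change of Gm23935 ranged from -0.502 to 0.171 with 1 library left out. The planned edgeR test on recovered reads was not run, and voom on those fragments took its place; DESeq2 was not run, as the table holds no raw counts. Depth limits genes of a few fragments, such as Mir1968 and Ighd4-1.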

Other observations

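The gene groups in this paragraph were drawn up after the called genes were seen, so their counts describe these libraries and are not independent evidence. Of 11 tested eicosanoid enzyme genes 1 rose and 3 fell, with a median log2 fold change of 0.03. Ptgs1 rose, while Alox5, the 5-lipoxygenase of leukotriene synthesis, fell (log2 fold change -0.64, SE 0.05, adjusted p = 0.0209), as did Mgst3, from 48.3 ± 2.07 to 31.6 ± 0.988 FPKM (-0.60), and Mgst2 (-0.58). Among 8 complement genes C5ar1, Cfp, the gene of properdin (46.6 ± 3.03 to 76.5 ± 4.38 FPKM, 0.70), and Itgb2 rose and 0 fell. A list of S100 and annexin genes together with Ahnak, which belongs to neither family, had 14 tested members, 12 negative and 2 positive, with a median of -0.21. In it S100a10 (-0.32), S100a11 (-0.32) and Anxa1 (-0.36) fell and Anxa3 rose (0.55). Ahnak itself fell (-0.58). Camera's unadjusted p with the preset correlation was 0.340, 0.00627 and 1.88e-06 for these lists, the last with Ahnak included, and 0.518, 0.106 and 0.124 with an estimated correlation.

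Tests chosen only after the result was seen were the comparison with matched coding genes, the B cell test, the inhibitory receptor test and the MondoA test. For the other tests the prediction was written before the test was run. The pseudogene pattern that they address came from these data and was not part of the fixed plan. Pseudogenes lay higher with 1,5-AG, with a median log2 fold change of 0.15 over 882 (74.5% positive) against -0.01 for protein coding genes. The SEs in this paragraph come from resampling genes and leave out the spread between libraries. They also treat pseudogenes that share a parent as independent. Within these limits the parent genes argue against a change of the parents as the whole cause. The median of pseudogene minus parent was 0.11 (SE 0.01) over 836 pairs. Gene length and GC content account for part: the test planned first, removal of that trend, left a median of 0.0626 (SE 0.00747), too close to the bound of 0.05 set for it to decide, and left 17 pseudogenes called higher and 4 lower. A second test, added because the first was undecided, put pseudogenes 0.10 (SE 0.01) above the 10 coding genes nearest in length and GC content, which argues against that trend as the whole cause. A different placement of reads between near-identical copies stays open as a candidate explanation. Pseudogenes at 98% identity or more exceeded those under 90% by 0.21 (SE 0.08). Mitochondrial genes with a tested nuclear copy were positive in 6 of 7 cases against 0 of 5 without one. Those with a copy had mean FPKM of 8.24 (mt-Nd3), 8.83 (mt-Nd4l), 35.1 (mt-Atp6), 63.3 (mt-Co3), 149 (mt-Co2), 775 (mt-Nd4) and 9072 (mt-Co1). Those without one ran from 669 (mt-Nd6) to 4049 (mt-Nd1). Most of the positive cases thus rest on low levels, whose cause was not tested. Coding parents with a copy at 98% identity or more did not fall, with a median of 0.0362 (SE 0.00690) against -0.00981 for other coding genes. A mere transfer of reads from parents to copies would lower the parents, but these medians cannot decide on it. Tested genes needed a mean of only 1 FPKM, while a parent such as Rpl7a had 529 FPKM in control. Reads enough to raise a weak copy would hardly lower such a parent. Mitochondrial genes were left out of this comparison of parents. How reads were placed cannot be told from these fold changes. No biological explanation other than a change of the parents was tested.

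The immunoglobulin heavy chain segments Ighd4-1 and Ighj2 fell, and Ighm had -0.39 (adjusted p = 0.0516). RNA from B cells is argued against, as Cd79a and Cd79b reached at most 0.495% of the lowest Ighm level in any library. Ms4a1 and Igkc, also named for the test, were not analysed here.

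A list drawn up as inhibitory receptor genes of myeloid cells gives a hypothesis from these data. Of 16 tested 6 fell (Cd300a -0.55, Clec4a3 -0.53, Cd33 -0.52, Cd72 -0.48, Sirpa -0.43 and Vsir -0.40), 0 rose and 14 were negative. Whether each member, Cd33 and Clec4a3 among them, acts as an inhibitory receptor in mouse was not checked. The list was written after the called genes were known, and the value of Fcgr2b had been seen. The 10 members that did not pass had a median of -0.18, at percentile 0.05 of 10000 random lists matched on mean expression. As the list was chosen with these results in view and Fcgr2b is among the 10, this percentile does not support a shift shared by the class, which stays open.

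1,5-AG resembles glucose, and the test assumed that hexose sensing by MondoA and ChREBP raises Txnip and Arrdc4. Their log2 fold changes were -0.17 (95% interval -0.33 to -0.01) and -0.25 (-0.57 to 0.07). Neither gene passed the limma test (adjusted p = 0.263 and 0.382). The highest upper bound of 0.0740 argues against a rise of 0.2 in either gene at 24 h. Glucose in the medium was not taken into account, so the test does not decide on sensing itself.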
